A study of Caenorhabditis elegans with 11 samples.

How the data were processed

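The data were 11 RNA-seq libraries of whole worms, in 4 groups: N2 (2 libraries), and the WT, 2KR and 4KR transgenic lines (3 libraries each). The labels call the libraries of a group biological repeats, and there was 1 line per transgene, so the substitutions and any other difference between the lines were not separable. The series text speaks of triplicates, while N2 had 2 libraries here. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, aligned with TopHat2 2.1.0 and compared with DESeq2 1.14.1. The genome build, the annotation, the program that counted reads and the use of strand in counting are not given in the sources used here. As deposited, each file holds a raw count per gene for 1 library, made by the authors from the aligned reads. Per the file headers, it also holds CPM, the count of a gene scaled by the authors to a fixed library total. Each file listed 47084 genes, of which 349 had no name in the files and keep their identifiers. Positions are from the Ensembl 115 annotation of WBcel235, matched by gene identifier, which gave 46474 genes a position.

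The counts were analysed from there in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3. Plots were drawn with matplotlib 3.10.9. Counts were scaled by TMM, genes with low counts were removed by filterByExpr with the groups given, and 14361 genes were left. CPM values in the text are scaled by TMM, except in the checks on the 4KR names, where CPM is of the library total. Genes were tested with the edgeR quasi-likelihood test in 1 fit with a term per group and no other term, and called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Log2 fold changes are of the group named first over the group named second, with the standard error of the fit, and the spread around group means is the SD. The comparisons were 2KR with WT, WT with N2, and 2KR with N2. Total counts ran from 21947014 to 30810301 in the 8 libraries compared. The intervals of the rol-6 ratios are 95% exact Poisson intervals, and they cover counting error only, since the reads carry no molecular identifiers.

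The lists, the 2KR and N2 comparisons, their tests and most alternatives were chosen before the data were examined. Chosen after were the overlap of the N2 comparisons with its alternatives, the fit of 8 libraries in place of 11, the fit of 2KR and WT alone with the block, and the tests of explanations in the closing section, except the splits of the libraries. The plan, from which there was 1 departure, was a single fit of all 11 libraries, and it included comparisons of 4KR with each other group and the overlap of 2KR and 4KR. Since the 4KR counts did not go with the names beside them, 8 libraries were fitted and no comparison with 4KR was made. The 4KR files share the row order of the WT files, and the N2 and 2KR files share another order. The fit of 11 libraries is among the alternatives.

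There were 32 gene lists, written from general knowledge: targets activated or repressed by DAF-16, heat shock chaperones, PMK-1 pathway immunity genes, C-type lectins, lysozymes and saposin-like proteins, epidermal antimicrobial peptides, cuticle collagens, molting genes, vitellogenins, sperm genes, oocyte and early embryo genes, germline and meiosis genes, muscle, neuronal and intestine genes, SKN-1 pathway and redox genes, cytochromes P450, UDP-glucuronosyltransferases, glutathione S-transferases, unfolded protein responses of the mitochondria and of the endoplasmic reticulum, insulin pathway components, insulin-like peptides, acetyltransferases and deacetylases, fat metabolism genes, autophagy genes, cytosolic ribosomal proteins, proteasome subunits, respiratory chain subunits, histones and osmotic stress genes. Some genes are in more than 1 list. Each list was compared with all other tested genes by limma camera with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. Camera with an estimated correlation and the rotation test fry stand beside it. Members that passed were counted over all genes and adjusted over the list alone.

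Genes were named by a rule. It takes daf-16 and rol-6, and in each comparison the 6 highest and the 6 lowest log2 fold changes among called genes with an average log2 CPM of at least 2 and no overlap of the groups. It adds, for the lists of DAF-16 targets, and for any other list called by camera or with at least 3 called members, up to 4 called members with the smallest p, or the 2 members with the smallest p where none was called. Genes outside the rule were chosen after their values were seen. In 2KR against WT they were nnt-1, mtl-1, hsp-12.6, tts-1, sod-3 and dod-23 of the DAF-16 targets. In that comparison they were also asp-1 and mtl-2 of the intestine genes and Y67D8A.2 and Y67D8A.9. In the comparisons with N2 they were dod-3 and sod-3. The remaining ones were gcy-23 and W08E12.8 near the stretch on chromosome IV, and those in the part on other observations.

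Whether replicate numbers pair the libraries was checked by the correlation, across genes, of deviations from group means. Between WT and 2KR libraries it was 0.41, 0.40 and 0.30 for equal numbers and below 0 for unequal ones. Values with the number as a block are thus given for that comparison where they change a call. They are also given for daf-16 and for some calls lost without 1 library. The fits with a library left out carried no block. For N2 the number in the title and the tag of the run differ in replicate 2, and the correlations did not settle which applies (0.08 and 0.12 by title, 0.16 and 0.08 by tag), so blocked values for N2 comparisons are given only among the alternatives. The alternatives were DESeq2 1.42.0 size factors, no filter on low counts, the DESeq2 Wald test, fits of only the groups compared, the replicate block by title and by tag, a fold of at least 2, and each library left out in turn. Where leaving out an N2 library left 1, that library was assumed to vary like the other groups. Simulated groups of unchanged genes that share the N2 libraries were used for the overlap of the N2 comparisons.

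The steps were tested on simulated data with 200 changed genes. Of genes changed 1.5-, 2- and 4-fold the test called 55.2%, 77.6% and 86.4% with the design of 2KR against WT, 44.8%, 67.2% and 84.8% with that of WT against N2, and 43.3%, 76.1% and 84.8% with that of 2KR against N2. Of the calls 8.75%, 5.76% and 7.48% were of unchanged genes, and 100% of the changed genes called had the right sign. A list lowered 1.5-fold was called in each design, also with an estimated correlation, and 2, 0 and 1 other lists were called with the preset one. The simulated genes varied independently, whereas the real DAF-16-activated list had an estimated correlation of 0.155 in 2KR against WT. The simulated lists thus do not show what camera with an estimated correlation can find in the real ones.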

Results

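RNA from whole worms was sequenced in 11 libraries, each made from about 1000 Caenorhabditis elegans on day 1 of adulthood, grown at 20 °C. Of these, 2 came from N2, the standard laboratory strain. The other 9 came from 3 lines, with 3 libraries each, in which a deletion in daf-16 was combined with an integrated daf-16 transgene. DAF-16 is the FOXO transcription factor that insulin signalling restrains. The transgene encoded GFP-tagged DAF-16 in its unaltered form (WT), with 2 lysines replaced by arginine (2KR), or with the same 2 and 2 more replaced (4KR). All 3 lines also carried a rol-6 plasmid, a marker that makes worms roll. The question behind the design is what the loss of lysines that can be acetylated does to gene expression in adults. Total counts ran from 21947014 to 30810301 over the 8 N2, WT and 2KR libraries and from 26018804 to 30405825 over the 3 4KR libraries.

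Among N2, WT and 2KR, the daf-16 transcript (WBGene00000912, chromosome I 10750498 to 10776703 of WBcel235), which the deletion and the transgene both alter, was most abundant in WT. It stood at 152 ± 10.2 CPM in N2 (SD, n = 2), 418 ± 30.1 CPM in WT (SD, n = 3) and 246 ± 38.6 CPM in 2KR (SD, n = 3). The 2KR line had a lower daf-16 level than WT (log2 fold change -0.77 ± 0.10 SE). The edgeR quasi-likelihood adjusted p was 0.0134 without the replicate block and 6.2e-04 with it. With 1 line per transgene, the lower level cannot be assigned to the substitutions. 2KR still stood above N2 (0.69 ± 0.12 SE, edgeR quasi-likelihood adjusted p = 0.00734). The first call was lost without WT replicate 3 (edgeR adjusted p = 0.0551), 2KR replicate 1 (0.0534) or 2KR replicate 3 (0.111), and the second without N2 replicate 1 (0.0634) or N2 replicate 2 (0.0893). Counts over the whole gene do not separate transgene reads from reads of any part of the gene that the deletion leaves, so they do not check the deletion itself. The rol-6 marker (WBGene00004397, chromosome II 8733050 to 8734239) followed the labels: it had 2 and 3 counts in the N2 libraries, 1569 to 1951 in the WT libraries and 3745 to 4469 in the 2KR libraries. Its ratio to N2 was 590 in WT (95% exact Poisson interval 252 to 1816) and 1304 in 2KR (559 to 4016), intervals that cover counting error only. Between the transgenic lines rol-6 rose by 1.15 ± 0.11 SE on the log2 scale in 2KR (edgeR quasi-likelihood adjusted p = 0.00179), opposite to daf-16.

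**Figure D1:**
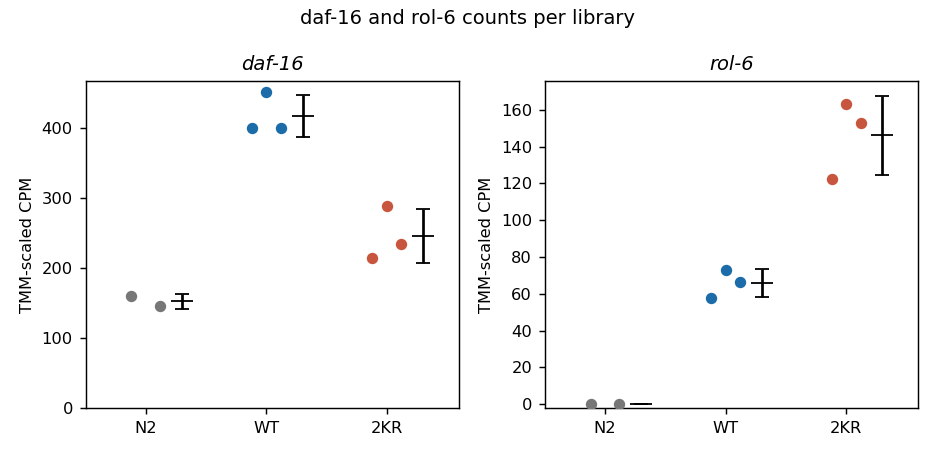
Level in CPM of daf-16 and rol-6 in each of the 8 N2, WT and 2KR libraries (points), with the mean and SD of each group beside them. daf-16 averaged 152 CPM in N2, 418 in WT and 246 in 2KR, while rol-6 was near 0 in N2 and higher in 2KR than in WT.

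In the 4KR files the counts did not go with the gene names beside them. Genes that every tissue needs in quantity were listed at low levels: the 75 cytosolic ribosomal protein genes had a median log2 ratio of 4KR to WT of -8.02 by name, against -0.07 for 2KR to WT. The yolk gene vit-2 averaged 19692 CPM in WT, and its row in the 4KR files held 81.7 CPM. Of the 100 most abundant genes in WT, 3 were among the 1000 most abundant in 4KR by name, against 100 in 2KR and 100 in N2. Across genes, the correlation of log2(CPM + 1) was 0.372 to 0.388 over the 24 pairs with 1 4KR library, 0.994 to 0.999 over the 28 pairs with none, and 0.994 to 0.997 over the 3 pairs of 4KR libraries. Sorted by level and without regard to name, the 4KR values differed from WT by a median absolute log2 difference of 0.0609 over the 10000 highest ranks, against 0.0153 for 2KR and 0.0391 for N2. No gene-level comparison was made with 4KR for this reason, and the 4KR rows named daf-16 and rol-6 are not read as levels of those genes.

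**Figure D2:**
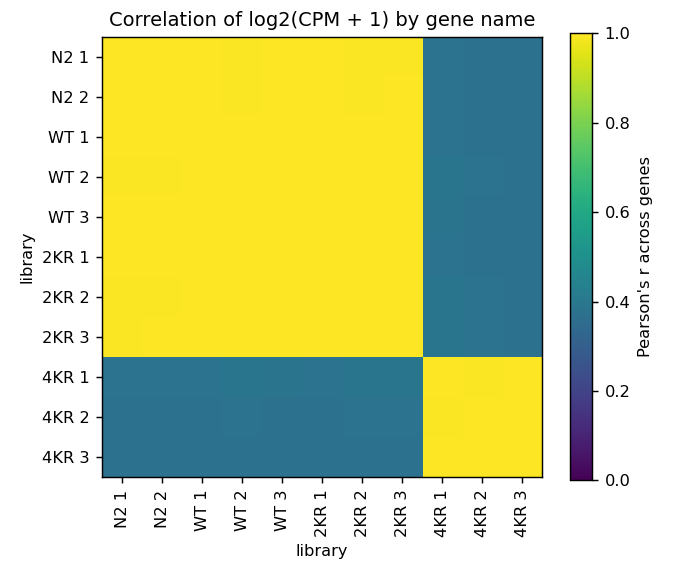
Correlation of log2(CPM + 1) across genes, matched by name, for every pair of the 11 libraries. Pairs of a 4KR library with a library of another group lie between 0.372 and 0.388, and all other pairs lie between 0.994 and 0.999.

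The comparison of 2KR with WT asks what the 2 lysine-to-arginine substitutions change. With 1 line per transgene it does not separate them from other differences of the lines. Without the replicate block, 35 of 14361 genes tested passed in 2KR against WT, 11 higher and 24 lower. With the replicate number as a block 221 passed, 131 higher and 90 lower. The gene that fell furthest among those named was Y73F8A.5, 16.24-fold lower at 1.01 ± 0.181 CPM in 2KR (SD, n = 3). In N2 Y73F8A.5 was at 0.664 CPM, close to 2KR, so for this gene WT was the line that stood apart from N2 (log2 fold change 4.63). T26C12.1 fell 5.55-fold, from 147 ± 9.04 to 26.5 ± 1.32 CPM (SD, n = 3 each), and its neighbour dmd-9, of the doublesex-related family, fell 4.09-fold, from 11.3 ± 1.06 to 2.76 ± 0.140 CPM. The gut protease gene cpr-5 (WBGene00000785, chromosome V 1132598 to 1134036) rose 1.90-fold, from 118 ± 7.45 to 225 ± 11.14 CPM. Known DAF-16-activated genes leaned down as a group, 19 of 21 members having a negative fold change (adjusted p = 0.315 with an estimated correlation), and dod-3 was the member that passed the test.

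Of the 35 genes in 2KR against WT, 13 changed at least 2-fold, 945 genes had an unadjusted p under 0.05, and 10 of the 35 have no symbol (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Among called genes with an average log2 CPM of at least 2, the largest rises beside rol-6 and cpr-5 were in fbxa-192, an F-box gene (log2 fold change 1.06 ± 0.15 SE), F22E5.1 (0.90 ± 0.13), the ammonium transporter gene amt-4 (0.81 ± 0.12) and the peroxisomal acyl-CoA oxidase gene acox-2 (0.67 ± 0.10). Under the same limit the largest falls were in Y73F8A.5 (-4.02 ± 0.20 SE, edgeR adjusted p = 9.44e-06), T26C12.1 (-2.47 ± 0.07, 7.48e-08), dmd-9 (-2.03 ± 0.12, 3.01e-05), F53B2.8 (-1.31 ± 0.15), fbxc-43 (-1.17 ± 0.15) and dod-3 (-1.16 ± 0.17). For cpr-5 the log2 fold change was 0.93 ± 0.06 SE (edgeR adjusted p = 0.000106). With the replicate number as a block the count was 221 genes, 131 higher and 90 lower, and all 35 were among them. The count was 124 without WT replicate 2, and between 7 and 22 without any other single library of the 2 groups. Y73F8A.5, T26C12.1, dmd-9, cpr-5 and rol-6 passed without each library in turn. By contrast, fbxa-192, F22E5.1, amt-4, acox-2 and dod-3 each lost their calls without at least 4 of the 6 libraries. Their edgeR adjusted p then ran from 0.053 to 0.205, in fits without the replicate block. With all libraries and the block, the same genes had edgeR adjusted p from 0.0015 to 0.00651. F53B2.8 lost its call without 2KR replicate 1 (edgeR adjusted p = 0.0534), and fbxc-43 without 2KR replicate 1 (0.0702) or 2KR replicate 3 (0.0885).

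Most DAF-16-activated genes had lower counts in 2KR than in WT. Of 21 measured members 0 rose and 1 fell over all genes tested, and 0 rose and 5 fell when adjusted over the list alone. Those 5 were dod-3, the transhydrogenase gene nnt-1 (log2 fold change -0.65 ± 0.16 SE), the metallothionein gene mtl-1 (-0.94 ± 0.24), the small heat shock gene hsp-12.6 (-1.19 ± 0.32) and the long non-coding RNA tts-1 (-0.66 ± 0.21). The superoxide dismutase gene sod-3, a standard DAF-16 reporter, had -0.41 ± 0.16, which did not pass. The median member had a log2 fold change of -0.14. The list was lower than other genes by camera with a preset correlation (limma, Benjamini-Hochberg adjusted p = 1.43e-08), and adjusted p = 0.315 with an estimated correlation. With the replicate block 2 members fell over all genes, dod-3 and nnt-1 (edgeR adjusted p = 0.0332). Of the 12 measured DAF-16-repressed genes, 9 had a positive fold change and 0 passed over all genes, against 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0179, and adjusted p = 0.655 with an estimated correlation). Without 2KR replicate 3 the camera adjusted p of the repressed list was 0.187. With the replicate block the peptide transporter gene pept-1 rose (0.50, edgeR adjusted p = 0.0125 against 0.191 without the block) and dod-22 fell (-0.93, 0.00997 against 0.0903), as a repressed gene that moved with the activated ones. The block also called dod-23 higher (0.51, 0.0352).

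**Figure D3:**
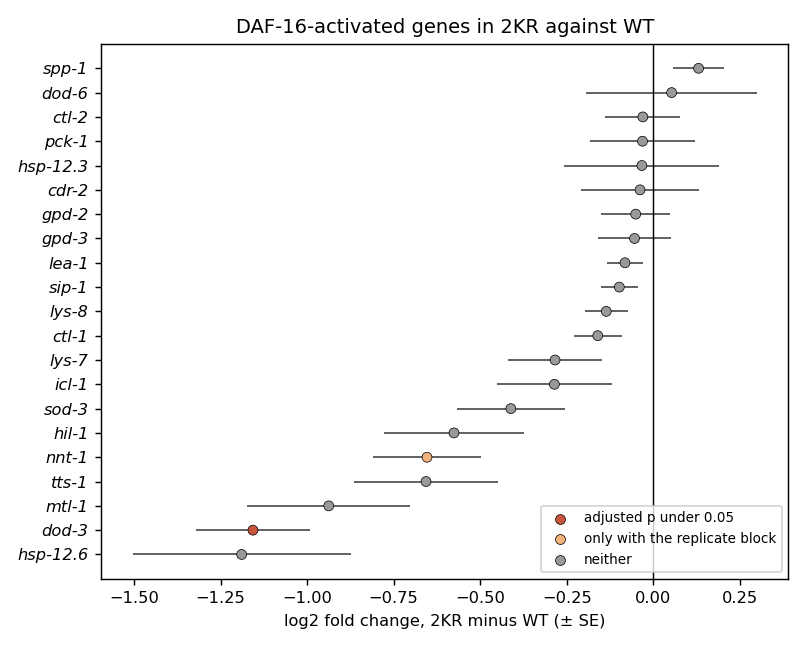
Log2 fold change of 2KR against WT for each of the 21 measured DAF-16-activated genes (points, with SE bars), from the edgeR fit of 8 libraries. Of the 21 genes, 19 lie below 0, and dod-3 at -1.16 is the 1 gene that passed over all genes tested.

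The lists of intestine and vitellogenin genes were called higher in 2KR by camera, and those of sperm genes and of oocyte and early embryo genes lower, with 0 of these 4 called with an estimated correlation. Of 15 intestine genes 12 had a positive fold change, 1 rose over all genes (cpr-5) and 2 rose when adjusted over the list alone (cpr-5 and the aspartyl protease gene asp-1, 0.31 ± 0.09 SE), with camera adjusted p = 1.55e-08, and adjusted p = 0.315 with an estimated correlation. Under the block 3 rose, asp-1 and mtl-2 beside cpr-5. All 6 vitellogenin genes, which encode yolk proteins, had positive fold changes, among them vit-1 (0.26 ± 0.06 SE) and vit-2 (0.10 ± 0.07). Of these 0 passed over all genes and 1 rose adjusted over the list alone (camera adjusted p = 0.00334, and adjusted p = 0.655 with an estimated correlation), and under the block vit-1 rose (edgeR adjusted p = 0.0158). Among 59 sperm genes 53 had a negative fold change, with a median of -0.33, and 0 passed, adjusted over the list alone too (camera adjusted p = 0.00595, and adjusted p = 0.83 with an estimated correlation). The members with the smallest p were ssp-37 (0.28 ± 0.15 SE) and spe-11 (-0.58 ± 0.33). The sperm list turned direction without WT replicate 1, where it was higher in 2KR (camera adjusted p = 0.0219), and lost its call without 2KR replicate 2 (0.192) or 2KR replicate 3 (0.379). Of 22 oocyte and early embryo genes 21 had a negative fold change, among them perm-4 (-0.10 ± 0.06 SE) and egg-2 (-0.08 ± 0.05), and 0 passed, adjusted over the list alone too (camera adjusted p = 0.00369, and adjusted p = 0.752 with an estimated correlation, and camera adjusted p = 0.692 without 2KR replicate 3).

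Collagen, C-type lectin and UDP-glucuronosyltransferase genes leaned upward in 2KR by small amounts, and the other lists of defence and detoxification genes were not called. Of 129 cuticle collagen genes 89 had a positive fold change, with a median of 0.13, among them col-143 (0.28 ± 0.06 SE) and col-160 (0.24 ± 0.06), and 0 passed, adjusted over the list alone too (camera adjusted p = 4.29e-04, and adjusted p = 0.655 with an estimated correlation). Without WT replicate 3 or 2KR replicate 2 the camera adjusted p of the collagens was 0.255 and 0.277, and under the block 5 rose. Of 96 C-type lectin genes, many of them induced in infection, 65 had a positive fold change, 0 passed over all genes and 1 rose adjusted over the list alone (camera adjusted p = 2.69e-04, and adjusted p = 0.655 with an estimated correlation). Under the block 4 lectin genes rose, clec-10 (0.64) and clec-66 (0.44) among them, and 2 fell. Of 59 UDP-glucuronosyltransferase genes, which conjugate toxins, 0 passed over all genes, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00548, and adjusted p = 0.655 with an estimated correlation). Under the block 5 of these rose, among them ugt-63 (0.63) and ugt-53 (0.85), and the list's call was lost without WT replicate 1 (camera adjusted p = 0.144) or 2KR replicate 3 (0.0961).

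Genes for making and degrading proteins leaned downward in 2KR by still smaller amounts. Of 75 cytosolic ribosomal protein genes 72 had a negative fold change, with a median of -0.07 (camera adjusted p = 2.36e-07, and adjusted p = 0.655 with an estimated correlation). Its leading members were rpl-9 (-0.15 ± 0.05 SE) and rpl-20 (-0.14 ± 0.05). Of 32 proteasome subunit genes 31 had a negative fold change, among them pas-3 (-0.10 ± 0.05) and pbs-1 (-0.13 ± 0.06), with camera adjusted p = 5.26e-04, and adjusted p = 0.752 with an estimated correlation. Of 51 histone genes 43 had a negative fold change, among them hil-1 (-0.58 ± 0.20) and his-59 (-0.36 ± 0.15), with camera adjusted p = 0.00261, and adjusted p = 0.494 with an estimated correlation. Histone copies are near identical, so single histone values are uncertain. Of 8 osmotic stress genes 7 had a negative fold change, among them hmit-1.1 (-0.62 ± 0.20) and tps-1 (-0.18 ± 0.08), with camera adjusted p = 0.00781, and adjusted p = 0.655 with an estimated correlation. The osmotic list lost its call without WT replicate 3 (camera adjusted p = 0.0742) or 2KR replicate 1 (0.0643). In these 4 lists 0 members passed, over all genes or adjusted over the list alone. The camera test with a preset correlation called 13 lists in all, 4 of the 10 splits of these 6 libraries into 3 and 3 gave at least as many, the real split included, and with an estimated correlation 0 lists passed.

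Of the 32 lists the other 19 were not called in 2KR against WT by camera. The adjusted p was 0.06 for respiratory chain subunits, 0.11 for germline and meiosis genes, 0.155 for insulin pathway components, 0.215 for autophagy genes and 0.245 for molting genes. It was 0.268 for SKN-1 pathway and redox genes, 0.273 for lysozymes and saposin-like proteins, 0.311 for cytochromes P450, 0.358 for epidermal antimicrobial peptides, 0.429 for neuronal genes and 0.437 for muscle genes. It was 0.513 for glutathione S-transferases, for the mitochondrial unfolded protein response and for fat metabolism genes, and 0.58 for the unfolded protein response of the endoplasmic reticulum. For acetyltransferases and deacetylases, the enzymes that add and remove acetyl groups, it was 0.93, for insulin-like peptides 0.952, and for heat shock chaperones and PMK-1 pathway immunity genes 0.982. By camera heat shock chaperones were called lower without WT replicate 2 and higher without 2KR replicate 2. Over all genes 0 members of these 19 lists passed the edgeR quasi-likelihood test. Adjusted over the list alone, 1 PMK-1 pathway gene rose and 2 fell, and 1 gene each fell in the lists of lysozymes, fat metabolism and autophagy. Under the block 2 PMK-1 pathway genes rose and 3 fell, 1 fat metabolism gene rose and 1 fell, and 2 lysozyme and saposin-like genes and 2 epidermal antimicrobial peptide genes fell. Under the block 1 gene each also fell among glutathione S-transferases, autophagy genes and the unfolded protein response of the endoplasmic reticulum, and 0 members of the other 12 lists passed.

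The genes T26C12.1 and dmd-9 lie side by side on chromosome IV. From the first to the last called gene at this place, positions 3222440 to 3263489 of the WBcel235 assembly, there were 4 tested genes, all called, and the next tested gene on either side was not (edgeR adjusted p = 0.923 and 0.811). Y67D8A.2, dmd-9 and T26C12.1 fell, Y67D8A.2 by 1.88-fold (log2 fold change -0.91 ± 0.06 SE, edgeR adjusted p = 1.50e-04). The short non-coding RNA Y67D8A.9, inside Y67D8A.2 and on the other strand, had 15 to 17 counts in the 2KR libraries and 0 in the WT and N2 libraries (edgeR adjusted p = 0.0225), a call lost without any 1 library but WT replicate 2 (0.0529 to 0.133). Strand use in the counting is not given in the sources used here, so these overlapping genes can share reads. Of the 4 genes, 0 were called in WT against N2. The 3 that fell were lower in 2KR than in N2 as well, T26C12.1 by 5.44-fold. Past the stretch, gcy-23 and W08E12.8 were also called lower in 2KR against N2 (log2 fold change -2.18 ± 0.31 SE and -2.69 ± 0.47). They had few counts in the 2KR libraries, 6 to 12 and 2 to 3. Neither was called in 2KR against WT (-1.06 and -1.84) or in WT against N2 (-1.12 and -0.85). Y67D8A.2, Y67D8A.9, gcy-23 and W08E12.8 are outside the rule for named genes and were chosen after their values were seen.

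**Figure D4:**
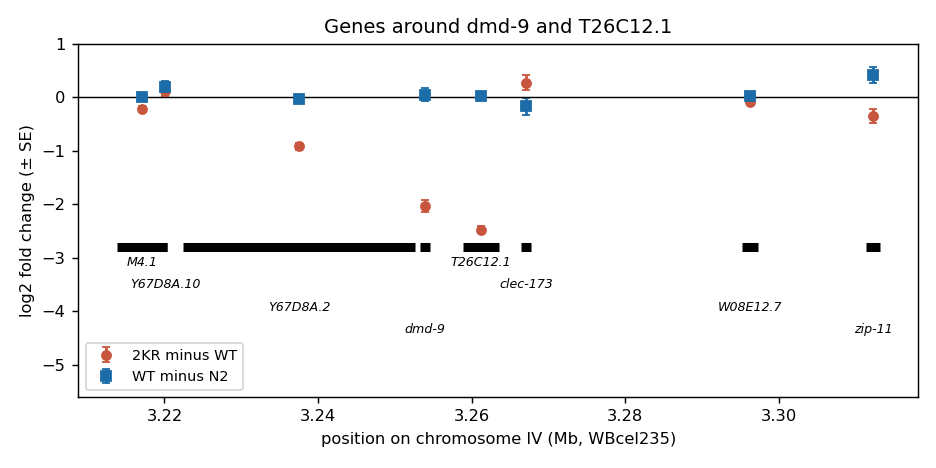
Log2 fold change of tested genes around the stretch on chromosome IV in 2KR against WT and in WT against N2, by position in megabases of the WBcel235 assembly (points, with SE bars). Only genes with a count of at least 100 in some WT or N2 library are drawn. Genes with fewer counts are not shown, among them the non-coding RNA inside Y67D8A.2, gcy-23 and W08E12.8. T26C12.1 at -2.47, dmd-9 at -2.03 and Y67D8A.2 at -0.91 are low in 2KR against WT, and near 0 in WT against N2.

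The comparison of WT with N2 shows how far the line with the unaltered transgene stood from the laboratory strain, through the deletion, the transgene, its marker and the line's own history together. Of 129 measured collagen genes 20 rose and 2 fell (camera adjusted p = 1.82e-09, and adjusted p = 0.878 with an estimated correlation). Among called genes with an average log2 CPM of at least 2, both col-147 and col-125 were among the 6 largest rises, from 1.26 ± 0.526 to 10.6 ± 4.73 CPM and from 0.708 ± 0.0557 to 5.06 ± 1.03 CPM (SD, n = 2 in N2 and 3 in WT). The largest fall under that limit was in Y106G6G.2, from 46.0 ± 1.42 to 0.723 ± 0.259 CPM. Genes activated by DAF-16 did not move one way, though the daf-16 level was 2.74-fold that of N2. In all, 584 of 14361 genes passed, 267 higher and 317 lower in WT.

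Of the 584 genes, 238 changed at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Under the same limit on average log2 CPM, the largest rises beside rol-6 and the 2 collagens were in Y73F8A.5 (log2 fold change 4.63 ± 0.26 SE), D1086.1 (3.85 ± 0.33) and ram-2 (2.47 ± 0.33), a gene known from mutants with altered male tail rays. Y73F8A.5 was at 0.664 ± 0.119 CPM in N2, so its level in 2KR, 1.01 CPM, was close to that of N2. After Y106G6G.2 (-5.99 ± 0.19, edgeR adjusted p = 1.47e-07) the largest falls under the limit were in T20F10.5 (-3.73 ± 0.20), WBGene00014774 (-2.97 ± 0.14), fmo-2, a flavin monooxygenase gene (-2.93 ± 0.61), the beta-galactosidase-like gene bgal-2 (-2.90 ± 0.13) and fbxa-192 (-2.58 ± 0.16). The N2 libraries differed widely in fmo-2 (19.6 ± 15.1 CPM), and its value without N2 replicate 1 was -1.79 (edgeR adjusted p = 0.395). It also lost its call without WT replicate 1 (0.0505) or WT replicate 3 (0.0528) and by DESeq2 (0.0705). The count of genes was 101 without N2 replicate 1 and 163 without N2 replicate 2, with 370 without WT replicate 2 and 330 without WT replicate 3. Of these named genes, col-147 lost its call without either N2 library (edgeR adjusted p = 0.0687 and 0.0797) and ram-2 without N2 replicate 1 (0.0705).

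Of the 129 cuticle collagen genes 95 had a positive fold change in WT against N2 and 34 a negative one, with a median of 0.65. Adjusted over the list alone, 41 rose and 7 fell, against 20 and 2 over all genes (camera adjusted p = 1.82e-09, and adjusted p = 0.878 with an estimated correlation). Further examples were col-167 (2.17 ± 0.36 SE) and col-3 (2.17 ± 0.37), both of which lost their calls without either N2 library (edgeR adjusted p from 0.0953 to 0.142). rol-6 is itself a collagen gene, and it is not a member of the list. Of 20 muscle genes all 20 had a positive fold change and 0 passed, adjusted over the list alone too, with the myosin genes myo-3 at 0.63 ± 0.19 and myo-2 at 0.89 ± 0.38 (camera adjusted p = 0.00548, and adjusted p = 0.989 with an estimated correlation). Of 47 neuronal genes 46 had a positive fold change, 1 rose over all genes and 0 adjusted over the list alone: unc-17, the acetylcholine transporter (1.21 ± 0.29), with camera adjusted p = 2.15e-04, and adjusted p = 0.989 with an estimated correlation. Without any 1 library of either group unc-17 lost its call (edgeR adjusted p from 0.0747 to 0.308). The muscle list lost its call without N2 replicate 1 (camera adjusted p = 0.361) or WT replicate 3 (0.0861). Of 59 sperm genes 49 had a negative fold change, yet the 1 that passed over all genes, spe-6, rose (0.80 ± 0.17), and 0 passed over the list alone (camera adjusted p = 0.00985, and adjusted p = 0.989 with an estimated correlation). The sperm list lost its call without N2 replicate 1 (camera adjusted p = 0.404), WT replicate 2 (0.0638) or WT replicate 3 (0.462), and spe-6 without any library but WT replicate 3 (edgeR adjusted p from 0.0699 to 0.246). Of 20 insulin-like peptide genes 18 had a positive fold change and 0 passed, adjusted over the list alone too, with ins-23 at 1.47 ± 0.45 and ins-33 at 2.09 ± 0.69 (camera adjusted p = 0.0134, adjusted p = 0.989 with an estimated correlation, and camera adjusted p = 0.163 without N2 replicate 1 and 0.0771 without WT replicate 2).

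Among DAF-16 targets, single genes moved both ways between WT and N2. Of 21 activated genes 1 rose and 2 fell over all genes, and 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.978). The antimicrobial lysozyme gene lys-7 rose (log2 fold change 0.87 ± 0.16 SE), and the desiccation protein gene lea-1 (-0.81 ± 0.06, edgeR adjusted p = 5.60e-05) and the small heat shock gene sip-1 (-0.58 ± 0.06, 6.19e-04) fell. sod-3 had 0.49 ± 0.18 and did not pass. Of 12 repressed genes, dod-24 rose (1.16 ± 0.18) and dod-23 fell (-1.05 ± 0.15), and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.969). The calls of lys-7, dod-24 and dod-23 were lost without N2 replicate 1 (edgeR adjusted p from 0.0687 to 0.151), and without N2 replicate 2 those of lys-7 (0.138) and dod-24 (0.0943). Of 8 osmotic stress genes 2 fell, over all genes and adjusted over the list alone, lea-1 and the inositol transporter gene hmit-1.1 (-1.45 ± 0.21), with camera adjusted p = 0.0019, and adjusted p = 0.878 with an estimated correlation. hmit-1.1 lost its call without N2 replicate 1 (edgeR adjusted p = 0.0834).

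Of 15 measured immunity genes that depend on the p38 kinase PMK-1, 13 had a negative fold change in WT against N2, 0 rose and 2 fell over all genes, clec-85 (log2 fold change -0.71 ± 0.11 SE) and clec-67 (-1.04 ± 0.19), and 1 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.00702, and adjusted p = 0.989 with an estimated correlation). Of 96 C-type lectin genes 2 rose and 8 fell, and adjusted over the list alone 5 rose and 11 fell (camera adjusted p = 0.59). Examples were clec-186 (-0.81 ± 0.09), clec-209 (-0.84 ± 0.10) and clec-170 (1.82 ± 0.25). The pseudogene clec-44 fell too (-4.11 ± 0.51), at low counts, from 0.919 CPM in N2 to 0.0488 in WT. Of 27 lysozyme and saposin-like genes 3 rose, with spp-2 (0.70 ± 0.11) and lys-7 among them, and 2 fell, ilys-3 (-3.25 ± 0.60) and ilys-2 (-3.83 ± 0.77). Adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.276). Leaving out N2 replicate 1 ended the calls of clec-85, clec-67, clec-170, spp-2, ilys-3 and ilys-2 (edgeR adjusted p from 0.0726 to 0.304), with ilys-3 at -2.096. Those of clec-67 (0.0871) and spp-2 (0.0797) were lost without N2 replicate 2, ilys-2 stood at -5.99 without WT replicate 1, and ilys-3 and ilys-2 also lost theirs without WT replicate 2 (0.0517 and 0.0507) or WT replicate 3 (0.0512 and 0.0774).

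Detoxification genes moved both ways. Of 59 UDP-glucuronosyltransferase genes 4 rose and 2 fell in WT against N2, and 6 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.978). ugt-64 rose (log2 fold change 0.81 ± 0.06 SE), as did ugt-63 (0.87 ± 0.15) and ugt-24 (1.00 ± 0.23), and ugt-25 fell (-1.17 ± 0.16). Of 57 cytochrome P450 genes 1 rose and 3 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.969): cyp-31A2 rose (0.45 ± 0.05), and cyp-13A2 (-1.23 ± 0.22), cyp-37A1 (-0.51 ± 0.12) and cyp-37B1 (-1.18 ± 0.28) fell. Of 51 histone genes, uncertain for their near-identical copies, 2 rose and 2 fell, and 5 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.978). They were his-53 (4.94-fold), his-19 (2.27 ± 0.50), the linker histone gene his-24 (-1.09 ± 0.16) and hil-3 (-0.81 ± 0.19), and his-24 stood at -0.72 without N2 replicate 1. In the fit without N2 replicate 1 the calls of ugt-63, ugt-24, cyp-13A2, cyp-37A1, cyp-37B1, his-53, his-19 and hil-3 were lost (edgeR adjusted p from 0.198 to 0.425). In the fit without N2 replicate 2 those of ugt-25, ugt-63, ugt-24, cyp-37A1, cyp-37B1, his-53, his-19 and hil-3 were lost (edgeR adjusted p from 0.0597 to 0.221). Leaving out 1 WT library ended calls of ugt-24, cyp-37A1, cyp-37B1, his-53, his-19 and hil-3 (edgeR adjusted p from 0.0525 to 0.133).

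The comparison of 2KR with N2 places the mutant line against the laboratory strain. The 2KR worms differed from N2 in 1114 of 14361 genes, 540 higher and 574 lower. Of 129 collagen genes 34 rose and 2 fell (adjusted p = 0.381 with an estimated correlation). Of 15 intestine genes 4 rose (adjusted p = 0.381 with an estimated correlation), with the protease gene cpr-5 at 225 ± 11.14 CPM in 2KR against 120 ± 7.19 in N2 (SD, n = 3 and 2), whereas 8 of 21 DAF-16-activated genes fell and 1 rose (adjusted p = 0.796 with an estimated correlation). Of 20 autophagy genes 4 fell (adjusted p = 0.796 with an estimated correlation). fmo-2 fell from 19.6 ± 15.1 to 0.583 ± 0.487 CPM.

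Of the 1114 genes, 405 changed at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Among called genes with an average log2 CPM of at least 2, the largest rises after rol-6 were in D1086.1 (log2 fold change 3.86 ± 0.32 SE), col-147 (3.54 ± 0.47), col-107 (10.6-fold), col-125 (2.89 ± 0.35) and ram-2 (2.69 ± 0.33). Under the same limit the largest falls were in Y106G6G.2 (-5.90 ± 0.19), fmo-2 (-5.06 ± 0.73), T20F10.5 (-3.41 ± 0.19), bgal-2 (-3.31 ± 0.13), WBGene00014774 (-2.72 ± 0.14) and the sugar transporter gene swt-3 (-2.71 ± 0.35). The count of genes was 162 without N2 replicate 1, and without N2 replicate 2 to 255 and without 2KR replicate 2 to 641. col-107 lost its call without either N2 library (edgeR adjusted p = 0.19 and 0.129), and fmo-2 without N2 replicate 1 (0.0587).

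Of 21 DAF-16-activated genes in 2KR against N2, 1 rose and 8 fell over all genes, and 4 rose and 10 fell adjusted over the list alone (camera adjusted p = 0.0084, and adjusted p = 0.796 with an estimated correlation). lea-1 (log2 fold change -0.89 ± 0.06 SE, edgeR adjusted p = 2.33e-05) and sip-1 (-0.67 ± 0.06, 2.02e-04) fell by about as much as in WT, mtl-1 fell (-1.19 ± 0.26), and the saposin-like gene spp-1 rose (0.42 ± 0.08). dod-3 fell as well (-0.80 ± 0.19), and sod-3 had 0.08 ± 0.18. Of 12 repressed genes dod-24 (1.21 ± 0.18), pept-1 (0.76 ± 0.13) and dod-17 (0.78 ± 0.20) rose and 0 fell, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.177). The activated list lost its call without N2 replicate 1 (camera adjusted p = 0.0818) or 2KR replicate 1 (0.0763). Calls of spp-1, mtl-1, dod-3, pept-1 and dod-17 were lost without N2 replicate 1 (edgeR adjusted p from 0.0764 to 0.281), and mtl-1 then stood at -0.61. Those of spp-1, dod-24, dod-3, pept-1 and dod-17 were lost without N2 replicate 2 (edgeR adjusted p from 0.0658 to 0.174). Leaving out 1 2KR library ended calls of mtl-1, dod-3 and dod-17 (edgeR adjusted p from 0.0501 to 0.0878).

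The 129 collagen genes had 101 positive fold changes and a median of 0.76 in 2KR against N2, with 56 rising and 5 falling adjusted over the list alone (camera adjusted p = 3.98e-13, and adjusted p = 0.381 with an estimated correlation). Beside col-147 and col-125, col-124 (0.53 ± 0.07 SE) and col-3 (2.57 ± 0.37) rose, and col-3 lost its call without N2 replicate 1 (edgeR adjusted p = 0.0652). Of 15 intestine genes 4 rose and 0 fell over all genes, and 6 rose and 0 fell adjusted over the list alone (camera adjusted p = 8.23e-05, and adjusted p = 0.381 with an estimated correlation). They were cpr-5 (0.90 ± 0.07, edgeR adjusted p = 9.67e-05), the intermediate filament gene ifb-2 (0.59 ± 0.07), the gut actin gene act-5 (0.43 ± 0.07) and the proton exchanger gene nhx-2 (0.47 ± 0.11). act-5 and nhx-2 lost their calls without N2 replicate 1 (edgeR adjusted p = 0.0841 and 0.165), and nhx-2 also without N2 replicate 2 (0.183) or 2KR replicate 3 (0.0725). Of 20 muscle genes all 20 had a positive fold change and tni-1, a troponin gene, rose (0.65 ± 0.14), 1 over all genes and 1 adjusted over the list alone (camera adjusted p = 0.00232, and adjusted p = 0.796 with an estimated correlation). Of 47 neuronal genes 2 rose, unc-17 (1.46 ± 0.29) and ric-4 (0.67 ± 0.18), and 1 adjusted over the list alone (camera adjusted p = 8.23e-05, and adjusted p = 0.796 with an estimated correlation). tni-1, unc-17 and ric-4 lost their calls without either N2 library (edgeR adjusted p from 0.0776 to 0.308), tni-1 also without 2KR replicate 3 (0.0523) and ric-4 without 2KR replicate 2 (0.104) or 2KR replicate 3 (0.113). The muscle list lost its call without N2 replicate 1 (camera adjusted p = 0.171). Of 59 sperm genes 52 had a negative fold change, with a median of -0.90, while spe-6 rose (0.65 ± 0.17) and 0 passed adjusted over the list alone (camera adjusted p = 8.23e-05, and adjusted p = 0.796 with an estimated correlation). The call of spe-6 was lost without any 1 library (edgeR adjusted p from 0.0698 to 0.255).

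The autophagy genes that fell in 2KR against N2 were sqst-1, the p62 cargo receptor (log2 fold change -0.66 ± 0.08 SE), epg-2 (-0.68 ± 0.13), atg-2 (-0.48 ± 0.12) and epg-9 (-0.48 ± 0.13). Of 20 members these 4 fell and 0 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.0196, and adjusted p = 0.796 with an estimated correlation). Of 8 osmotic stress genes 2 fell, lea-1 and hmit-1.1 (-2.08 ± 0.21), and 4 fell adjusted over the list alone (camera adjusted p = 2.04e-05, and adjusted p = 0.381 with an estimated correlation). Of 26 fat metabolism genes 3 rose and 2 fell, and 3 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.353). The fatty acid elongase genes elo-5 (0.95 ± 0.14) and elo-2 (0.64 ± 0.11) rose, and the desaturase genes fat-5 (-0.70 ± 0.13) and fat-7 (-2.09 ± 0.41) fell. Without N2 replicate 1 the autophagy list (camera adjusted p = 0.103) and the calls of epg-2, atg-2, epg-9, elo-5, elo-2, fat-5 and fat-7 were lost (edgeR adjusted p from 0.0635 to 0.277). Without N2 replicate 2 those of atg-2, epg-9, elo-2, fat-5 and fat-7 were lost (edgeR adjusted p from 0.0616 to 0.169), and without 1 2KR library those of atg-2 and epg-9 (0.06 to 0.114).

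Of 15 PMK-1 pathway genes in 2KR against N2, 1 rose and 4 fell, and 2 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.0106, adjusted p = 0.796 with an estimated correlation, and camera adjusted p = 0.0552 without 2KR replicate 1). clec-85 (log2 fold change -0.79 ± 0.11 SE), irg-2 (-1.68 ± 0.26) and the pump gene catp-3 (2.47-fold lower) fell, and clec-17 rose from 0 counts in N2 to 0.463 ± 0.0259 CPM. Of 96 C-type lectin genes 8 rose and 9 fell, and 14 rose and 10 fell adjusted over the list alone (camera adjusted p = 0.374), with clec-170 4.61-fold higher, clec-44 at -4.17 ± 0.51 and clec-266 at -1.31 ± 0.17. Of 27 lysozyme and saposin-like genes 1 rose and 3 fell, spp-1 up and ilys-3 (-3.31 ± 0.60), ilys-2 (-3.33 ± 0.71) and lys-8 (-0.29 ± 0.07) down, and 6 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.55). Without N2 replicate 1 the calls of clec-85, irg-2, catp-3, clec-17, ilys-3, ilys-2 and lys-8 were lost (edgeR adjusted p from 0.0657 to 0.295), with ilys-3 at -2.15. Without N2 replicate 2 those of catp-3 (0.0635), clec-17 (0.0835) and lys-8 (0.127) were lost, and without 1 2KR library those of ilys-2 and lys-8 (edgeR adjusted p from 0.0561 to 0.0926).

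Detoxification enzymes in 2KR against N2 moved both ways. Of 59 UDP-glucuronosyltransferase genes 9 rose and 5 fell, and 10 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.177), with ugt-64 (log2 fold change 0.82 ± 0.06 SE), ugt-63 (2.82-fold) and ugt-58 (0.53 ± 0.07) up and ugt-25 (-1.17 ± 0.16) down. Of 35 glutathione S-transferase genes 5 rose and 3 fell, and 5 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.177), with gsto-1 (0.49 ± 0.09), gst-13 (0.63 ± 0.11) and gst-26 (0.59 ± 0.12) up and gst-7 (-0.35 ± 0.07) down. Of 16 SKN-1 pathway and redox genes 1 rose and 2 fell, over all genes and adjusted over the list alone, gst-13 up and gst-7 and gst-38 (-1.02 ± 0.22) down (camera adjusted p = 0.451). Of 57 cytochrome P450 genes 3 rose and 3 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.804), with cyp-31A2 (0.43 ± 0.05) up and cyp-32B1 (-1.16 ± 0.22), cyp-37B1 (-1.37 ± 0.28) and cyp-37A1 (-0.56 ± 0.12) down. Without N2 replicate 1 the calls of gsto-1, gst-13, gst-26, gst-7, gst-38, cyp-32B1, cyp-37B1 and cyp-37A1 were lost (edgeR adjusted p from 0.0841 to 0.236), and without N2 replicate 2 those of gsto-1, gst-13, gst-26, gst-7, gst-38 and cyp-37A1 (0.0571 to 0.139). Leaving out 1 2KR library ended calls of gst-38, cyp-37B1 and cyp-37A1 (edgeR adjusted p from 0.0517 to 0.063).

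Other gene groups in 2KR against N2 were mixed. Of 17 endoplasmic reticulum stress genes 2 rose, ero-1 (log2 fold change 0.32 ± 0.05 SE) and ckb-2 (0.48 ± 0.09), and 1 fell, the stress regulator xbp-1 (-0.33 ± 0.06), with 2 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.881). Of 75 cytosolic ribosomal protein genes rpl-39 rose (0.56 ± 0.10) and rpl-24.2 fell (-0.36 ± 0.08), 1 and 1 adjusted over the list alone too (camera adjusted p = 0.0106, and adjusted p = 0.796 with an estimated correlation). Of 32 proteasome subunit genes 29 had a negative fold change and 0 passed, adjusted over the list alone too, with rpn-8 at -0.13 ± 0.05 and pbs-6 at -0.13 ± 0.05 (camera adjusted p = 0.0418, and adjusted p = 0.796 with an estimated correlation). Of 20 insulin-like peptide genes 17 had a positive fold change and 0 passed, adjusted over the list alone too, with ins-13 at 2.12 ± 0.57 and ins-26 at 1.09 ± 0.39 (camera adjusted p = 0.0196, and adjusted p = 0.796 with an estimated correlation). Of 51 histone genes, uncertain for their near-identical copies, 2 rose and 7 fell, and 4 rose and 10 fell adjusted over the list alone (camera adjusted p = 0.177), with his-24, hil-3 (-0.91 ± 0.19), his-65 (-0.97 ± 0.21) and hil-8 (-1.06 ± 0.24) among those that fell. Without N2 replicate 1 the ribosomal (camera adjusted p = 0.224), proteasome (0.162) and insulin-like (0.123) lists lost their calls, as did the genes xbp-1, ckb-2, rpl-39, rpl-24.2, hil-3, his-65 and hil-8 (edgeR adjusted p from 0.0673 to 0.238). Without N2 replicate 2 those 7 genes and ero-1 lost theirs (edgeR adjusted p from 0.0595 to 0.141), as did the proteasome list (camera adjusted p = 0.0512). Without 2KR replicate 2 the ribosomal, proteasome and insulin-like lists lost their calls (camera adjusted p = 0.0785, 0.139 and 0.0914), the proteasome list lost it without 2KR replicate 3 too (0.141), and leaving out 1 2KR library ended calls of rpl-24.2, hil-3, his-65 and hil-8 (edgeR adjusted p from 0.0509 to 0.0742).

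Both transgenic lines differed from N2 in many of the same genes. Of 14361 genes tested in both comparisons, 484 were called the same way, 217 higher and 267 lower, and 0 in opposite directions. Independent lists of those sizes would share 22.7, and 20 simulations of unchanged groups against the same N2 libraries shared a mean of 0.05 and at most 1. The simulated groups held no changed genes, so a low shared count was fixed in advance. It does not show how the shared N2 libraries add to the 484. Across genes, which are not independent replicates, the correlation of the log2 fold changes was 0.885 against 0.639 in the simulations, and their covariance was 0.304 against 0.0522, a difference of 0.252. The 2 N2 libraries cannot be split into parts of 2, so part of the excess in shared calls may come from the shared controls.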

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

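The tests on the 4KR names, on the chromosome IV stretch and on the daf-16 level were chosen after the results were seen, and the counts over other splits of the libraries were planned.

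The 4KR libraries, which no comparison uses, held a signal far above that of N2 under many gene names. In each of the 3 libraries 4212 names stood at 10 times the highest N2 level or more (with a floor of 1 CPM), against 1 name in the 2KR libraries. The values argue against worms of another genotype, stage or tissue, since ribosomal protein genes, which every tissue needs, had a median log2 ratio of 4KR to WT of -8.02. They are consistent with counts listed under the names of other genes: sorted without names, the 4KR levels followed those of WT to a median absolute log2 difference of 0.0609. Sorted levels of N2 also followed those of WT, to 0.0391, so this match alone cannot tell genotypes apart. Which step put the names out of place was not tested. The 4KR counts were not read in the row order of the N2 and 2KR files. No biological explanation for these values was tested beyond another genotype, stage or tissue.

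The genes T26C12.1, dmd-9 and Y67D8A.2 on chromosome IV fell together in 2KR, with Y67D8A.9 beside them. Chance placement of genes called independently is argued against. As many as 4 called genes within 10 neighbouring tested genes came in a share of 0.0001 of 10000 shuffles, the smallest they can give. The shuffles take genes as independent, but Y67D8A.9 overlaps Y67D8A.2 and can share its reads. The share may thus be too small, and the 3 genes that fell were not tested without Y67D8A.9. Loss of the whole stretch from a line that is homozygous is argued against too, since T26C12.1, which fell most, kept 18.01% of its WT level and dmd-9 kept 24.4%. Another DNA difference of the 2KR line at that place stays open: of the 3 genes lower in 2KR than WT, 0 were called lower in WT than N2. With 1 line per transgene it cannot be told apart from an effect of the 2 substitutions.

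The lean of DAF-16-activated genes to lower levels in 2KR than WT came with a lower daf-16 level. A candidate explanation is that less daf-16 transcript gave less DAF-16, and the biological one in the design is the loss of the lysines. If the daf-16 level were the cause, the list should not lie below N2, since daf-16 in 2KR was above N2. The list in 2KR against N2 had adjusted p = 0.796 by camera with an estimated correlation, against 0.0084 with the preset one. This test cannot decide between the explanations, since it takes the list to follow daf-16 counts between N2 and the lines. WT also stood above N2 in daf-16, and there the list was not called (camera adjusted p = 0.978). Counts over the whole gene also do not separate transgene reads from reads of what the deletion leaves. Both explanations stay open.

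The 6 WT and 2KR libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes changed in 2KR against WT, 1 of the 10 splits, the real one, gave as many as 35, and the highest of the others was 6. Of the splits that, like the real one, part all 3 replicate pairs, the real one called 221 genes with the replicate block and the others 0. For gene lists, 4 of the 10 splits gave at least the 13 of the real one, and the highest of the others was 20. The DAF-16-activated list was called by camera in 4 of the 9 other splits (adjusted p = 1.29e-05, 0.00298, 0.00306 and 0.0402), with a median of up to 0.20, against 1.43e-08 and -0.14 in the real one. Of the 3 others that part all 3 pairs, 1 called the list (0.00306, against 0.115 and 0.173). The list's mean log2 CPM, less its mean over 8 libraries, was 0.09, 0.17 and 0.20 in WT replicates 1 to 3 and -0.28, -0.08 and -0.12 in 2KR. The 3 pairs thus differ the same way, and with so few splits variation between libraries is left open for this list.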

How the results depend on the processing

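The fit of 11 libraries was the plan, and it became an alternative after the data were seen, when 8 were fitted instead. The fit of 2KR and WT alone with the block and the alternatives for the overlap were chosen after the data were seen, and the other alternatives were planned. The alternatives set in advance for comparisons with 4KR and for the overlap of 2KR and 4KR were not run, as the 4KR counts do not go with their names.

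The counts of changed genes were 35 (2KR against WT), 584 (WT against N2) and 1114 (2KR against N2). They stayed within 1.5 times of these with DESeq2 size factors and in the fit of 11 libraries. Of the same calls, DESeq2 size factors kept 35, 571 and 1106, and the fit of 11 kept 27, 385 and 651. The fit of 11 includes the 4KR counts under names they do not go with, so its totals do not show stability. In 2KR against WT the count was 99 with no filter, 22 with only the 2 groups, 221 with the block by title, 319 with the block by run tag, 286 with only the 2 groups and the block, and 95 by DESeq2. In WT against N2 it was 911 with no filter, 1794 with the block by title and 1455 by tag. In 2KR against N2 it was 2695 with the block by title and 2457 by tag. A fold of at least 2 left 13, 238 and 405. Without 1 library the counts ran from 7 (without 2KR replicate 1) to 124 (without WT replicate 2) in 2KR against WT, from 101 (without N2 replicate 1) to 464 (without WT replicate 1) in WT against N2, and from 162 (without N2 replicate 1) to 986 (without 2KR replicate 1) in 2KR against N2. The blocks by title and by tag pair the WT and 2KR libraries alike and differ only in the place of N2 replicate 2. Other causes were not tested, except that a fold of 2 can only lower a count. Having fewer libraries does not account for the 124 without WT replicate 2.

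Camera with an estimated correlation called 0, 0 and 0 lists in the 3 comparisons, and fry 0, 0 and 3, against 13, 7 and 12 with the preset correlation. In 2KR against WT the heat shock chaperones were called higher with the block by tag (camera adjusted p = 0.0218, 4 genes higher), against 0.884 and 0 genes by title. With an estimated correlation the call by tag was lost (camera adjusted p = 0.584). Title and tag pair the WT and 2KR libraries alike, so the blocks differ only in the place of N2 replicate 2. In WT against N2 the DAF-16-activated genes had 7 higher and 2 lower with the block by title and 3 and 2 by tag, against 1 and 2 without, and in 2KR against N2 they had 6 and 9 by title and 4 and 10 by tag, against 1 and 8. With the block by title, heat shock chaperones (0.00102 in WT against N2 and 0.00572 in 2KR against N2), epidermal antimicrobial peptides (0.0401 and 0.0131) and, in WT against N2, vitellogenins (0.0401) were called lower. With an estimated correlation in that block these calls were lost (camera adjusted p = 0.856 in WT against N2 and 0.79 in 2KR against N2). With the block by tag, fat metabolism genes were called lower in WT against N2 (0.0155, and 0.622 with an estimated correlation). In that block calls were lost by insulin-like peptides (0.102 in WT against N2 and 0.126 in 2KR against N2) and, in 2KR against N2, by ribosomal proteins (0.0654) and proteasome subunits (0.17). With only the 2 groups, calls were lost by insulin-like peptides in WT against N2 (0.065) and proteasome subunits in 2KR against N2 (0.0787). In the fit of 11 libraries, autophagy genes (0.0549), ribosomal proteins (0.0702) and proteasome subunits (0.131) lost theirs in 2KR against N2. In 2KR against N2 the sperm genes had 2 higher and 11 lower with the block by title and 1 and 16 by tag, against 1 and 0 without, the neuronal genes 14 and 9 higher against 2, the muscle genes 8 and 7 higher against 1, and the ribosomal protein genes 14 and 12 lower against 1. In WT against N2 the collagen genes had 57 higher and 10 lower with the block by title and 37 and 6 by tag, against 20 and 2, and the muscle genes 7 and 6 higher, against 0. Of these myo-3 had edgeR adjusted p = 3.43e-04 with the block by title and 2.62e-04 by tag. Without 1 library camera called from 10 to 19 lists in 2KR against WT, from 4 to 8 in WT against N2 and from 6 to 13 in 2KR against N2. The overlap of the N2 comparisons was 1448 genes with the block and 548 by DESeq2, against 484. Beyond the place of N2 replicate 2, the cause was not tested.

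Named genes and those chosen later, gcy-23 and W08E12.8 aside, kept direction and side of the threshold in 517 of 627 values in 2KR against WT. The counts were 612 of 705 in WT against N2 and 902 of 1044 in 2KR against N2. In these comparisons 0, 6 and 2 values were reversed. By the DESeq2 Wald test, calls in WT against N2 were lost by fmo-2, unc-17 (DESeq2 adjusted p = 0.108), ugt-24 (0.0745) and spe-6 (0.053). In 2KR against N2 they were lost by dod-17 (DESeq2 adjusted p = 0.0891), spe-6 (0.115), his-65 (0.075) and hil-8 (0.0768). All reversed values were of genes that had not passed. In WT against N2, Y67D8A.2 was 0.0163 with the block by tag and from -0.0880 to 0.0292 without 1 library, T26C12.1 from -0.0533 to 0.119 and dmd-9 from -0.0251 to 0.125. In 2KR against N2, sod-3 was -0.0155 with the block by title and from -0.0732 to 0.170 without 1 library. The cause was not tested.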

Other observations

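The test around daf-16 and the neighbour counts were chosen after the results were seen, as were all genes named in this part except Y106G6G.2.

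The p38 kinase genes pmk-1, pmk-2 and pmk-3, which lie side by side on chromosome IV with islo-1 (8136389 to 8151266), were lower in both transgenic lines than in N2. From N2 to WT and 2KR, mean levels were 51.7, 20.2 and 19.9 CPM for pmk-1, 30.8, 6.50 and 6.35 CPM for pmk-2, 46.2, 9.60 and 10.1 CPM for pmk-3, and 14.3, 5.03 and 4.48 CPM for islo-1. The log2 fold changes of WT over N2 were -1.35, -2.24, -2.27 and -1.51 in that order, each called. Between 2KR and WT they were -0.03, -0.03, 0.07 and -0.17, none called. The transporter gene haf-6 on chromosome I (1162880 to 1175809) rose in both lines, from 7.02 CPM in N2 to 36.98 in WT and 37.9 in 2KR. Near Y106G6G.2 on chromosome I, Y106G6G.4 fell as well, by -4.14 on the log2 scale in WT and -4.58 in 2KR, as did Y106G6G.6, from 12.2 CPM in N2 to 0.278 in WT and 0.266 in 2KR.

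On chromosome V (16518183 to 16603202), 6 of 10 neighbouring tested genes were called in WT against N2, in a share of 0.0051 of shuffles, with F36D3.7, srw-34, F36D3.15 and F36D3.16 lower and Y32B12B.4 and T03E6.8 higher. In 2KR against N2, 7 of 10 neighbours from 16516472 were called (share 0.0119).

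A hypothesis for changes shared by the transgenic lines is that DNA around daf-16 came along with the daf-16 deletion. Of 300 genes tested within 1 Mb of daf-16, 15 were called in WT against N2, which is 5.0% against 3.96% elsewhere, and as many in a share of 0.275 of rotations of the calls along the genome. Y106G6G.2 and Y106G6G.4 are among the 15, and Y106G6G.6 is not. Only genes with a position were counted, which were 566 of the 584 called in WT against N2. In 2KR against N2 it was 21 genes, 7.0% against 7.69% elsewhere (share 0.597), and in 2KR against WT 0 by edgeR. In WT against N2 calls were more frequent near daf-16 than elsewhere, by no more than rotations often gave. In 2KR against N2 they were less frequent. Most of the 15 genes were also called in 2KR against N2, and both comparisons use the same N2 libraries. Calls shared by the 2 lines, which the hypothesis concerns, were not tested by themselves, so the hypothesis stays open.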
